A study of Homo sapiens with 4 samples.

How the data were processed

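Polyadenylated RNA of H1299 cells was measured in 4 libraries, 2 treated with PBS and 2 with ginseng nanoparticles. Per the labels' protocols, libraries were made from 300 ng of total RNA with a TruSeq stranded mRNA kit. The deposited files hold whole-number read counts per Ensembl gene, 1 file per library, not normalized. Per the submitters' processing notes, the tools named are bcl2fastq 2.20, cutadapt 3.5, STAR 2.7.6a, Picard and HTSeq 2.0.2, with the genome build GRCh38. The annotation release and the strand setting are not given in the sources used here. Groups were taken from the treatment label. The titles of the nanoparticle libraries also carry the word control, which contradicts that label, and the treatment label was followed.

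Each file had 61541 gene rows. Rows for reads given to no gene (no feature, ambiguous, not aligned, not uniquely aligned) were left out of library sizes and tests. Their shares of reads were 14.8% and 14.5% in PBS replicates 1 and 2 and 14.3% and 13.7% in nanoparticle replicates 1 and 2. Symbols came from a table of gene names for 61369 rows, and 159 of the remaining 172 rows were named from GENCODE 29. Coordinates, lengths and GC content came from GENCODE 29 on GRCh38, whose release may differ from the one used for counting. Replicates were compared first: the chi-square per degree of freedom over genes was 1.98 between the PBS libraries and 2.19 between the nanoparticle libraries, so none was treated as a copy of another.

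Genes were filtered with filterByExpr, libraries were scaled by TMM, and nanoparticle was tested against PBS with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The estimated biological coefficient of variation was 2.46%. Standard errors were derived from the fitted coefficient and its F statistic. Depth per library was between 22252686 and 24979081 counts on genes. Shares of reads or counts have Wilson intervals at the 95% level with a half-width of at most 0.0136 percentage points, which cover counting error only.

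Before the data were examined, 35 gene lists were fixed, on migration and matrix, mechanics and uptake, metabolism, stress, inflammation, growth and death, RNA quality, and markers of other cell types. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. They were tested again with the correlation estimated from the data, and with fry, with adjustment over the lists. With the correlation estimated, camera used the 2 residual degrees of freedom of the fit, so a list passes less easily whatever its correlation. The genes named in the text followed a rule fixed at the same time: the 10 largest increases and the 10 largest decreases among genes past the threshold with a symbol that is not a clone name, a mean of at least 5 CPM and no overlap between groups; up to 4 members with the smallest p for each list described; and 10 migration markers. Some items that the rule or the lists cover are not reported here. Alternatives fixed at the same time were other scalings (RLE, upper quartile, total counts), no low-count filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out mitochondrially encoded genes, and leaving out each library.

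After the data were seen, a trend with transcript length was found and 3 alternatives were added. In each library a robust spline (4 degrees of freedom, MASS 7.3.60.0.1) of log2 CPM on length, or on length and GC content, was fitted over genes above 5 CPM and removed as an offset. The length of a gene was first taken as the union of its exons. This was replaced by the principal transcript after its result had been seen, since the union can include retained introns, and both are reported. The GC trend was also removed on its own, and gene lists were compared with other genes above 5 CPM of like abundance or length. A length was known for 98.2% of tested genes.

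The procedure was tested on simulated counts with the real means and library sizes and 200 changed genes. These were drawn only from genes with a mean of at least 100 counts, and the lysosome and autophagy list was raised besides. For nanoparticle against PBS with 15597 simulated genes tested, 60% of 1.2-fold, 98% of 1.5-fold, and 100% of 2-fold and 3-fold changes were recovered, and 6.54% of calls were false. With a simulated length trend left in (15568 genes tested), 48.7% of calls were false, and 6.85% with the trend removed. Figures were drawn with matplotlib 3.10.9.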

Results

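RNA was sequenced from H1299 cells, a human lung carcinoma line, that had been treated with nanoparticles made from ginseng or with phosphate-buffered saline (PBS) as the control. The libraries were stranded and made from polyadenylated RNA, with 2 libraries per group. Counts on genes came to 22252686 and 22456882 in the PBS libraries and to 24979081 and 24863313 in the nanoparticle libraries. The labels give no dose, no exposure time and no plant part for the nanoparticles. Nothing in them says that the replicates came from separate cultures, so every p-value measures the spread between these libraries, which may be technical. The study concerned the effect of the nanoparticles on cancer cell migration, and the sequencing addressed transcripts related to it.

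With nanoparticles HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose from 109 ± 5.54 to 244 ± 54.8 CPM (counts scaled by library size; mean ± SD, n = 2 per group), a log2 fold change of 1.16 with a standard error of 0.086 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.19e-07). CASP9, the initiator caspase of the mitochondrial death pathway, rose from 26.6 ± 1.498 to 46.8 ± 3.42 CPM (log2 0.81, SE 0.063, edgeR adjusted p = 1.78e-07). KITLG, the ligand of the receptor KIT, rose from 17.6 ± 2.07 to 28.8 ± 1.68 CPM (log2 0.71, SE 0.078). SLC7A11, the cystine transporter subunit, rose by a log2 fold change of 0.73 and PTPRN, a secretory granule protein, by 0.73. MT-ND6, a mitochondrially encoded subunit of respiratory complex I, rose by 1.17 on the log2 scale, with nanoparticle libraries at 15.9 and 30.3 CPM against 9.53 and 11.1 in PBS, and by 0.63 without nanoparticle replicate 2. The other genes with the largest increases were GFI1 (log2 0.56), GCLM (0.55), the pseudogene FER1L4 (0.54) and the nuclear long non-coding RNA MALAT1 (0.54). Without nanoparticle replicate 2 the log2 fold change was 0.31 for FER1L4 (adjusted p = 0.416) and 0.22 for MALAT1 (adjusted p = 0.145).

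The largest decrease among genes of at least 5 CPM was in NUAK2, a kinase related to AMPK, which fell from 23.1 ± 0.495 to 15.6 ± 2.21 CPM (log2 -0.57, SE 0.085, edgeR adjusted p = 0.000625). Next came RASL10A (log2 -0.54), the metallothionein MT1X (-0.52), the Notch target NRARP (-0.43) and ELFN1 (-0.42). DUSP1, a phosphatase of MAP kinases, fell from 51.3 ± 2.55 to 39.1 ± 2.56 CPM (log2 -0.39), and the WNT ligand WNT5B fell from 75.9 ± 7.04 to 58.1 ± 1.98 CPM (log2 -0.39). ZFPM1 (log2 -0.39), HOMER3 (-0.36) and PRR7 (-0.34) completed the 10 genes. In human genome build GRCh38, with GENCODE 29 gene models, HMOX1 lies on chromosome 22 from 35380361 to 35394214, CASP9 on chromosome 1 from 15490832 to 15526534, KITLG on chromosome 12 from 88492793 to 88580851 and NUAK2 on chromosome 1 from 205302059 to 205321791. Exons of CASP9 overlap those of CELA2B on the opposite strand, those of SLC7A11, KITLG and PTPRN also overlap opposite-strand genes, and the strand setting of the counting is not given in the sources used here.

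**Figure D1:**
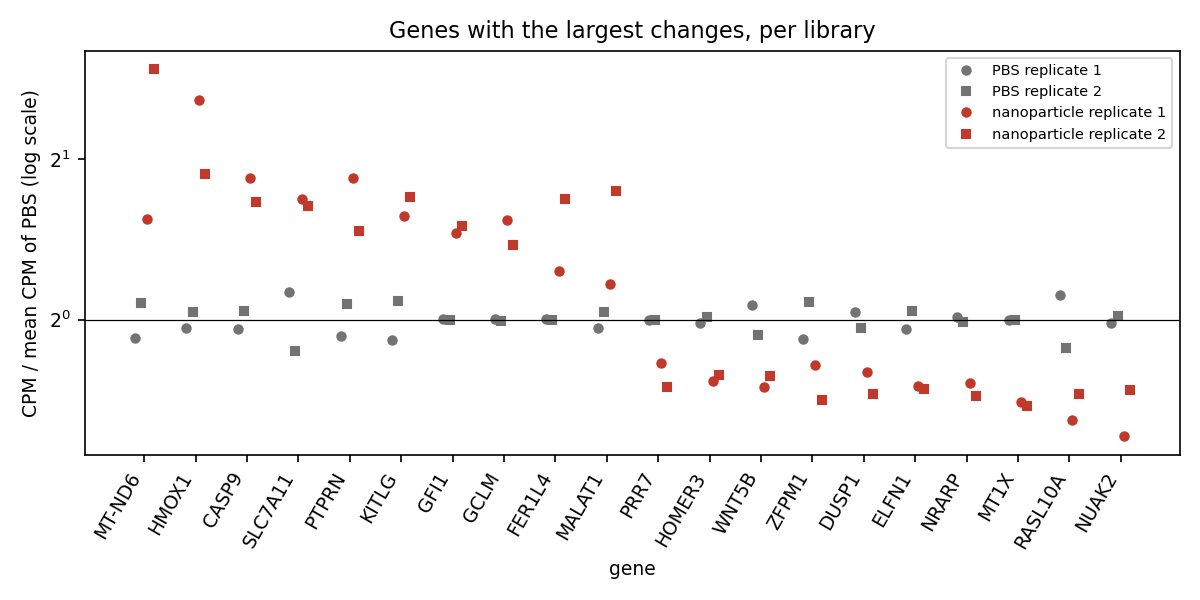
CPM of each library divided by the mean CPM of the PBS libraries, on a log scale, for the 10 genes with the largest increase and the 10 with the largest decrease. Circles and squares are replicates 1 and 2, grey for PBS and red for nanoparticle; HMOX1 stood at 282 and 205 CPM in the nanoparticle libraries against 105 and 113 CPM in PBS.

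Across the transcriptome, 407 of 15778 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 276 higher and 131 lower with nanoparticles. The median fold change of the genes that passed was 1.16. A change of at least 1.5-fold was seen for 7 higher genes, which were HMOX1, MT-ND6, CASP9, SLC7A11, PTPRN, KITLG and AC135178.5. It was also seen for 5 lower genes, ISLR2, AC090409.1, HMGA1P2, LBX2 and FCHO2-DT, all below 5 CPM and named after their values were seen. With upper-quartile scaling 223 genes were higher and 190 lower. No gene, including every gene named here, passed without PBS replicate 1 (lowest adjusted p = 0.212, 1562 genes at an unadjusted p under 0.05) or without PBS replicate 2 (lowest adjusted p = 0.139, 1672 genes), while 200 passed without nanoparticle replicate 1, 76 without nanoparticle replicate 2 and 90 by DESeq2's Wald test. Of the genes with the largest changes, RASL10A, MT1X, NRARP and HOMER3 did not pass without nanoparticle replicate 1, and these as well as GFI1, FER1L4, MALAT1, ZFPM1 and PRR7 did not pass without nanoparticle replicate 2.

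The genes that rose had longer transcripts than those that fell. The median length of the principal transcript was 7410 bases for the 276 higher genes and 1853 bases for the 131 lower genes, against 2856.5 for all tested genes. Over 11110 expressed genes ordered by length in 10 bins, the median log2 fold change went from -0.063 in the shortest bin to 0.082 in the longest. Spearman's rank correlation between length and fold change was 0.42 across these genes, which are not independent replicates. Fold change also went with GC content (Spearman's rank correlation -0.33 across the same genes), with a median GC of 42.6% for the higher and 56.7% for the lower genes. With the length trend of each library removed, an alternative added after the data were seen, 208 genes passed, 121 higher and 87 lower, and 155 of the 407 genes were among them. HMOX1, CASP9, KITLG, SLC7A11, PTPRN, MT-ND6, GFI1, GCLM, MALAT1, NUAK2, RASL10A, ELFN1, DUSP1, ZFPM1, WNT5B, HOMER3 and PRR7 still passed after this removal, whereas FER1L4 (log2 0.50, adjusted p = 0.055), MT1X (log2 -0.43, 0.0826) and NRARP (log2 -0.39, 0.0772) did not, with fold changes close to those before it. With length and GC trends both removed FER1L4 passed (adjusted p = 0.0392), while RASL10A (log2 -0.43, adjusted p = 0.095), ZFPM1 (log2 -0.34, 0.0766) and PRR7 (log2 -0.21, 0.109) did not.

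**Figure D2:**
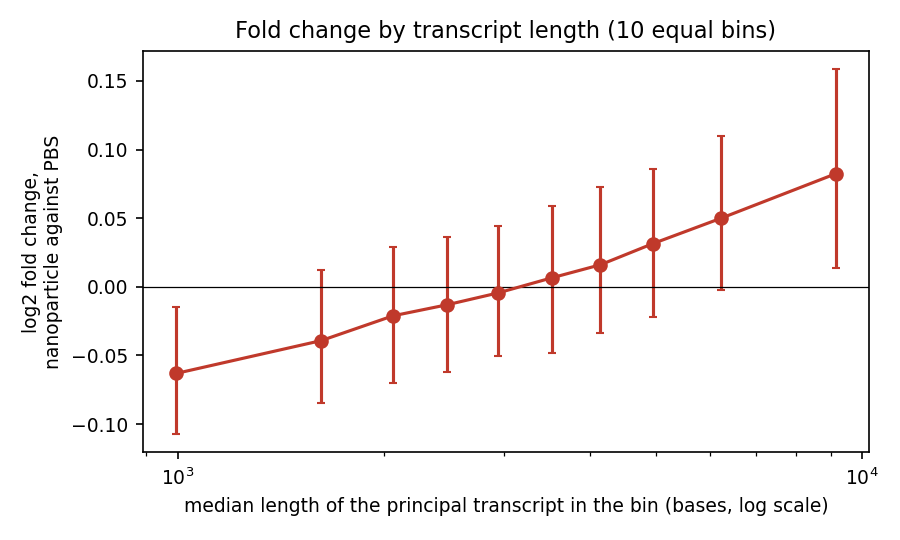
Median log2 fold change, nanoparticle against PBS, of expressed genes in 10 bins of equal size by the length of the principal transcript in bases (log axis). Bars span the interquartile range of the genes in each bin; the medians go from -0.063 to 0.082.

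Genes under the control of NRF2, the transcription factor of the antioxidant response, shifted upward as a list (camera with a preset correlation of 0.01, adjusted p = 6.65e-10, and adjusted p = 0.497 with an estimated correlation). Of 32 tested members 6 passed the threshold, all higher, and 8 passed when adjusted over the list alone, all higher. The median log2 fold change of the 32 was 0.057, and 9 members had a fold change below 0. TXNRD1, the cytosolic thioredoxin reductase, rose from 572 ± 17.6 to 756 ± 1.56 CPM (log2 0.40, SE 0.026, edgeR adjusted p = 2.09e-08). GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, rose from 85.4 ± 0.535 to 125 ± 9.57 CPM (log2 0.55, SE 0.045). HMOX1, SLC7A11, TRIM16L (log2 0.39) and OSGIN1 (log2 0.17) were the other members that passed. NQO1, also a target of NRF2, did not pass in the reported test. Over 17 alternatives its log2 fold change was between 0.080 and 0.14, and it passed in 2. Without nanoparticle replicate 1, and likewise without nanoparticle replicate 2, 5 of the 6 members passed.

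For the migration question, 2 of the 10 markers fixed beforehand passed the test, both lower. VIM, the intermediate filament protein of mesenchymal cells, fell from 2354 ± 50.2 to 2209.6 ± 30.8 CPM (log2 -0.092, SE 0.019, edgeR adjusted p = 0.0137). MMP14, a membrane-bound collagenase, fell from 270 ± 2.63 to 246 ± 2.63 CPM (log2 -0.13, SE 0.031, adjusted p = 0.0231). With the length trend removed VIM had a log2 fold change of -0.066 (adjusted p = 0.0996), and it passed with length and GC trends both removed (0.0392), and neither gene passed without nanoparticle replicate 1 or nanoparticle replicate 2. FN1 (log2 0.11, SE 0.035), ZEB1 (0.14, SE 0.056), CDH2 (-0.076, SE 0.053), MMP9 (-0.14, SE 0.10), PTK2, which encodes focal adhesion kinase (0.020, SE 0.032), MMP2 (0.061, SE 0.15) and SNAI2 (0.069, SE 0.43) did not pass, and the standard errors of MMP2 and SNAI2 leave larger changes open in either direction. Over the alternatives the log2 fold change ran from 0.029 to 0.15 for FN1 and from 0.079 to 0.20 for ZEB1. It ran from -0.14 to -0.011 for CDH2, and for PTK2 it changed sign (-0.043 to 0.044). CDH1, the epithelial cadherin, had 8 and 1 counts in the PBS libraries and 5 and 6 in the nanoparticle libraries, too few to be tested.

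**Figure D3:**
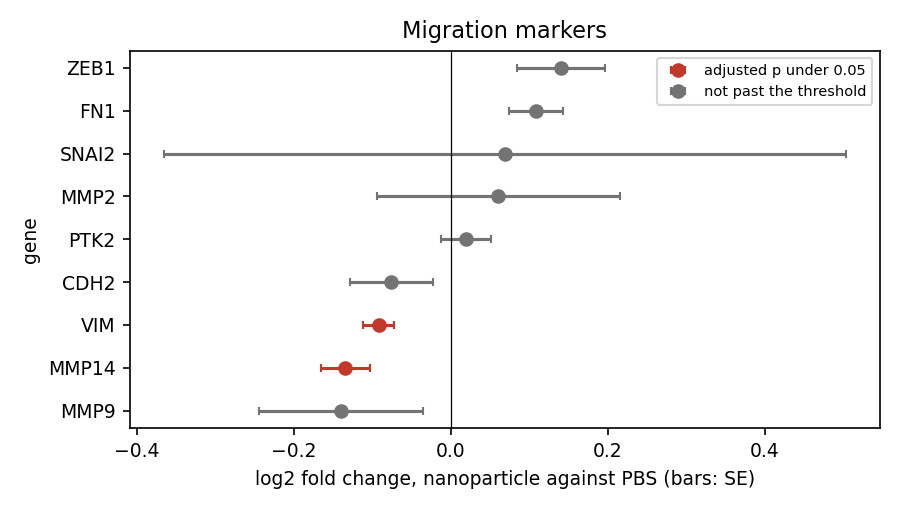
Log2 fold change with its standard error, nanoparticle against PBS, of the 9 migration markers that were tested (2 libraries per group). VIM at -0.092 and MMP14 at -0.13, in red, passed an adjusted p of 0.05; the genes in grey did not.

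None of the migration lists passed the reported list test, and some passed in 1 or more alternatives. Among matrix proteases and their inhibitors 4 of 30 members passed, all lower, with MMP14 among them (list adjusted p = 0.127, shifted downward at 0.0446 with the stricter filter and 0.0495 without nanoparticle replicate 1, and adjusted p = 0.722 with an estimated correlation). The urokinase gene PLAU fell from 755 ± 8.62 to 678 ± 1.44 CPM (log2 -0.15), and the collagenase gene MMP1 fell from 105 ± 1.96 to 92.0 ± 3.17 CPM (log2 -0.18). With the length trend removed MMP1 had a log2 fold change of -0.15 (adjusted p = 0.0552), and it passed with length and GC trends both removed (0.0178). With the union of exons as length MMP1 did not pass (log2 -0.13, adjusted p = 0.104). Of 22 EMT and mesenchymal genes 3 passed, all lower, among them VIM and the receptor tyrosine kinase AXL (log2 -0.095 for AXL; list adjusted p = 0.311). By DESeq2's Wald test without independent filtering MMP14 (adjusted p = 0.0787), VIM (0.096), AXL (0.103) and MMP1 (0.136) did not pass. In the actin cytoskeleton list TMSB10, PFN1 and RHOC of 54 members passed, all lower (list adjusted p = 0.11), and with the length trend removed none of the 3 did: the log2 fold change went from -0.11 to -0.019 for TMSB10 (adjusted p = 0.819), from -0.089 to -0.038 for PFN1 (0.51) and from -0.13 to -0.10 for RHOC (0.162). The actin list shifted downward with upper-quartile scaling (adjusted p = 0.0443), by limma-voom (0.0152), without mitochondrial genes (0.0436) and without PBS replicate 1 (0.0161), and had adjusted p = 0.722 with an estimated correlation. None of 34 integrin and focal adhesion genes passed (list adjusted p = 0.397). Adjusted over the list alone, 6 integrin and focal adhesion, 9 actin, 5 EMT and 6 protease genes passed. With the length trend removed the integrin list shifted downward (adjusted p = 0.00333, and adjusted p = 0.403 with an estimated correlation), as did the YAP/TAZ target list (adjusted p = 0.00457, and adjusted p = 0.573 with an estimated correlation), which had an adjusted p of 0.146 in the reported test and 0.0137 without nanoparticle replicate 2.

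Ribosomal protein genes and nuclear genes of oxidative phosphorylation shifted downward as lists (camera adjusted p = 2.17e-18 and 4.06e-12, and adjusted p = 0.497 for each with an estimated correlation). Of 74 ribosomal protein genes 12 passed the threshold and 65 passed adjusted over the list alone, all lower, with a median log2 fold change of -0.077. RPL13 fell from 1057 ± 5.59 to 969.5 ± 43.2 CPM (log2 -0.12, SE 0.026, edgeR adjusted p = 0.013), and RPS26, RPL32 and RPL26 fell by 0.13, 0.11 and 0.20 on the log2 scale. Over 17 alternatives RPL13 passed in 13, RPS26 and RPL32 in 8 each and RPL26 in 7. The log2 fold change of RPL13 was -0.079 without nanoparticle replicate 2. RPS26, RPL32 and RPL26 did not pass with the length trend removed (log2 -0.081, -0.081 and -0.14; adjusted p = 0.239, 0.147 and 0.213). Reads of these genes can be shared with their processed pseudogenes, so single members are uncertain. Of 68 oxidative phosphorylation genes 2 passed, ATP5MF (log2 -0.19) and COX5A (-0.14), and 8 passed adjusted over the list alone, all lower (list median -0.070). With the length trend removed neither passed, at log2 -0.091 for ATP5MF (adjusted p = 0.384) and -0.093 for COX5A (0.216). Both lists hold short transcripts, with median lengths of 1029 and 1058.5 bases, and with the length trend removed their medians were -0.017 and -0.033 (adjusted p = 0.000996 and 0.00333 at the preset correlation, and adjusted p = 0.598 and 0.403 with an estimated correlation).

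The 13 mitochondrially encoded mRNAs shifted upward (camera adjusted p = 5.83e-06, adjusted p = 0.722 with an estimated correlation). MT-ND6 and MT-ND5 passed the threshold, and 6 members passed adjusted over the list alone, all higher. MT-ND5 went from 157 ± 36.7 to 217 ± 53.4 CPM (log2 0.47). Its log2 fold change was 0.20 without nanoparticle replicate 2 (adjusted p = 0.542), 0.25 without PBS replicate 1 (0.686) and 0.73 without PBS replicate 2 (0.47). The mitochondrial share of gene counts was 0.272% and 0.381% in the PBS libraries and 0.328% and 0.454% in the nanoparticle libraries, so that the groups overlapped. The list adjusted p was 0.982 without PBS replicate 1, with the direction turned, 0.576 without nanoparticle replicate 2 and 0.157 without a low-count filter.

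Cholesterol synthesis genes shifted downward (camera adjusted p = 0.0022, adjusted p = 0.722 with an estimated correlation). Of 25 members INSIG1, the sterol-regulated retention protein, and SQLE, squalene epoxidase, passed, with log2 fold changes of -0.20 and -0.13, and 4 passed adjusted over the list alone, all lower. G1/S and DNA replication genes also shifted downward (adjusted p = 0.0022, adjusted p = 0.497 with an estimated correlation). Of 45 members CCND1, which encodes cyclin D1, fell from 524 ± 8.73 to 457 ± 5.25 CPM (log2 -0.20, SE 0.027, edgeR adjusted p = 0.000259), and UNG, a uracil-DNA glycosylase, fell by 0.16 on the log2 scale. These 2 were also the members that passed adjusted over the list alone. Without nanoparticle replicate 2 the cholesterol list had an adjusted p of 0.0533. SQLE had a log2 fold change of -0.13 and an adjusted p of 0.0515 with the length trend removed, and it passed with length and GC trends both removed (0.0294). With the union of exons as length neither SQLE (log2 -0.12, adjusted p = 0.0579) nor UNG (log2 -0.12, adjusted p = 0.0791) passed.

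Genes of the unfolded protein response shifted upward (adjusted p = 0.0296, adjusted p = 0.497 with an estimated correlation), with CREB3L2 (log2 0.35) and the ER chaperone HSPA5 (log2 0.10) passing out of 36, the same number as adjusted over the list alone. HSPA5 had a log2 fold change of 0.088 with the length trend removed (adjusted p = 0.0722), and it passed with length and GC trends both removed (0.0306) and with the union of exons as length (0.0107). Apoptosis and death genes shifted upward too (adjusted p = 0.0389, adjusted p = 0.497 with an estimated correlation). In that list CASP9 and PMAIP1, which encodes the BH3 protein NOXA (log2 0.23), passed out of 36, and 3 passed adjusted over the list alone, all higher. The unfolded protein list did not pass without PBS replicate 1 (adjusted p = 0.05003), PBS replicate 2 (0.0658) or nanoparticle replicate 1 (0.109), and the apoptosis list did not pass without PBS replicate 1 (0.143), PBS replicate 2 (0.137) or nanoparticle replicate 1 (0.0659). With upper-quartile scaling the adjusted p was 0.052 and 0.0511 for the 2 lists, and limma-voom gave 0.105 for the apoptosis list. NF-kB and inflammatory cytokine genes lay at the threshold (adjusted p = 0.0505), with LIF (log2 -0.31), NFKBIA (-0.25) and NFKB2 (-0.14) lower out of 26. This list shifted downward in 8 of 16 alternatives, among them the stricter filter (adjusted p = 0.0105), the length removal (0.0119) and the fit without nanoparticle replicate 2 (0.00062). It did not without nanoparticle replicate 1 (0.508) or either PBS library (0.138 and 0.254), and had adjusted p = 0.722 with an estimated correlation.

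**Figure D4:**
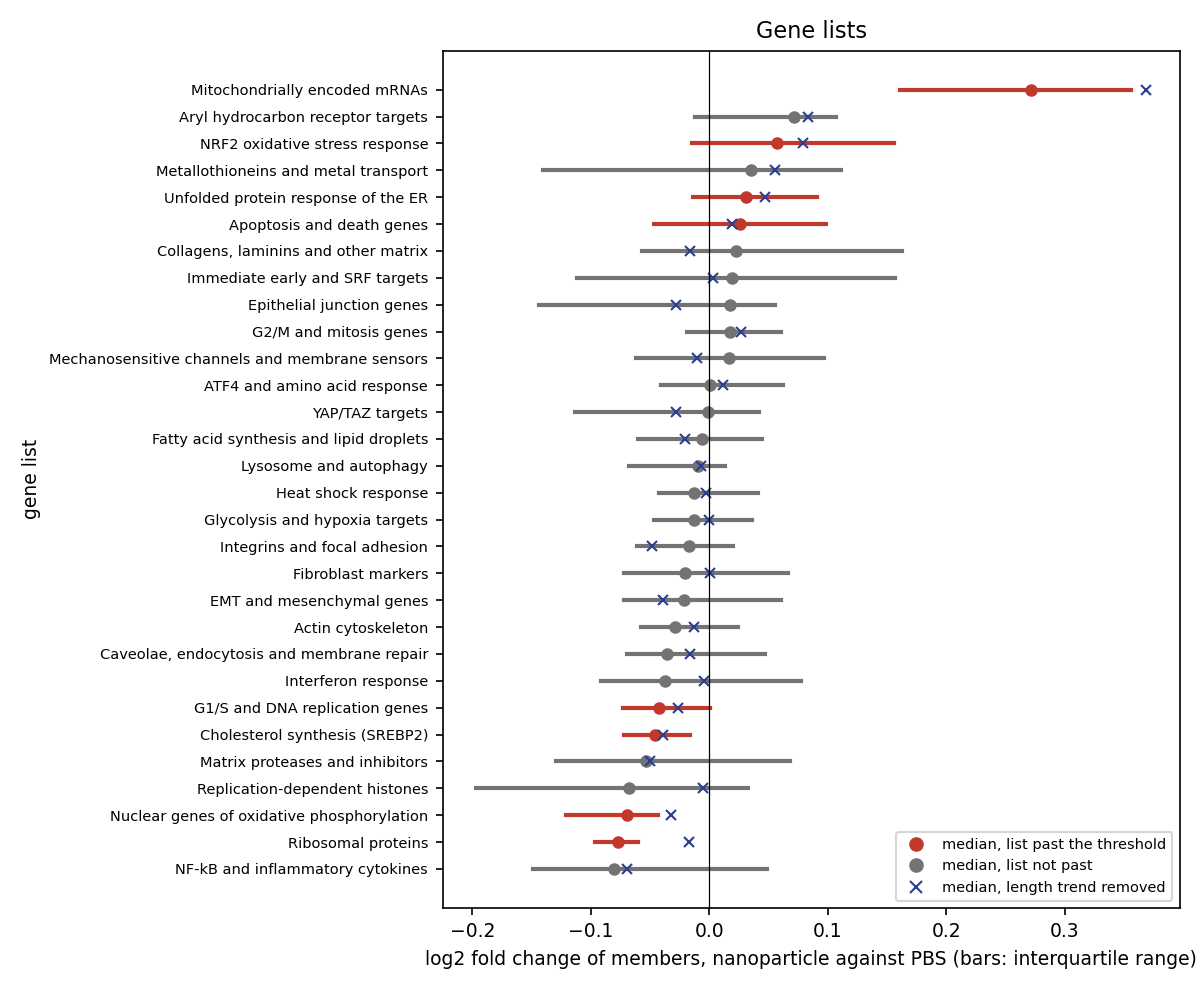
Median log2 fold change of the tested members of the gene lists, nanoparticle against PBS, with bars for the interquartile range of members. Red marks the 8 lists that passed the list test at the preset correlation, and crosses give the median with the length trend removed; the ribosomal protein median moved from -0.077 to -0.017.

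Library quality values were not tested, since an exact two-sided permutation test of 2 against 2 cannot give a p below 0.33. Genes with at least 1 count numbered 23133 and 23154 in the PBS libraries and 23359 and 23615 in the nanoparticle libraries. The share of reads given to no gene was 14.8% and 14.5% in PBS and 14.3% and 13.7% with nanoparticles. Reads that aligned to more than 1 place were 4.75% and 4.64% in PBS, 4.51% in nanoparticle replicate 1 and 3.51% in nanoparticle replicate 2. The 10 most abundant genes took 3.12% and 3.19% of gene counts in PBS and 3.11% and 3.07% with nanoparticles.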

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

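One signal outside the gene counts was higher with nanoparticles, and no explanation was tested for it. Reads that aligned to no annotated feature made up 2.61% ± 0.243 (mean ± SD, n = 2) of reads in the nanoparticle libraries and 2.38% ± 0.0555 in the PBS libraries. The values were 2.34% and 2.42% in PBS, 2.44% in nanoparticle replicate 1 and 2.78% in nanoparticle replicate 2. It was picked out because the 95% Wilson intervals of both nanoparticle libraries, which cover counting error only, lay above those of both PBS libraries. Most of the difference lay in nanoparticle replicate 2. Only shares higher with nanoparticles were searched for. By the same intervals, reads not aligned (2.97% and 2.67% in PBS, 2.54% and 2.57% with nanoparticles) were lower with nanoparticles. So were reads not uniquely aligned (4.75% and 4.64% in PBS, 4.51% and 3.51% with nanoparticles).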

How the results depend on the processing

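The length removals were chosen after the data were seen; the other settings were not. None of the 79 named genes past the threshold turned direction in any setting; 46 did not pass without nanoparticle replicate 1, 57 without nanoparticle replicate 2 and 52 by DESeq2 without independent filtering. Counts of genes stayed within 1.5 times of 407 with RLE, upper-quartile or total-count scaling, limma-voom, the stricter filter (although 212 genes were then lower) and without mitochondrial genes. Without a low-count filter 0 genes passed, 0 of them higher, lower or changed at least 1.5-fold, with 2297 at an unadjusted p under 0.05 and a prior of 1.85 degrees of freedom for the spread, against 18.3 in the reported fit. DESeq2 called 90 genes (66 higher, 24 lower, 5 at least 1.5-fold) without and 121 (88, 33 and 3) with independent filtering; all were among the 407, and the cause was not tested. Leaving out single libraries gave 0 to 200 genes, 0 to 155 higher, 0 to 45 lower and 0 to 20 at least 1.5-fold, the lone library being assumed to vary like the others. The 0 came without either PBS library, where the prior fell to 4.45 and 4.13 degrees of freedom. With the replicate number as a block 759 genes passed, 487 higher, 272 lower and 37 at least 1.5-fold. Over all genes same-numbered libraries did not deviate together (correlation 0.00619). The mitochondrial share did, at 0.272% (PBS) and 0.328% (nanoparticle) in replicates 1 and 0.381% and 0.454% in replicates 2. With the block MT-CO1 and MT-CYB passed (log2 0.35 and 0.40, edgeR adjusted p = 2.73e-28 and 3.58e-27), in a fit with 1 residual degree of freedom. The prior for the spread was infinite in that fit, so the spread was shared across genes rather than fitted to each. Neither these p-values nor the 759 calls show that the numbers mark pairs. Whether the numbers mark pairs therefore stays open. Removing the length trend left 208 genes (121 higher, 87 lower). Removing length and GC trends left 264 (150 higher, 114 lower), 171 of them among the 407. With the union of exons as length 287 passed and 13 lists passed. With an estimated correlation 0 of the 8 lists passed, as against 8 in the reported test. That version of camera rests on 2 residual degrees of freedom, so the loss alone does not show that members move together. The G1/S list had an estimated correlation of -0.0042, below the preset 0.01, yet its unadjusted camera p went from 0.00043 to 0.052. Estimates were higher for other lists, such as 0.17 for the NRF2 and 0.14 for the ribosomal protein list. The highest was 0.95, for the mitochondrially encoded list, so the preset of 0.01 was far too low for that list. Fry in 1 direction gave an adjusted p of 0.0456 for the unfolded protein list alone. Its mixed test, of change in either direction, passed for most lists (lowest adjusted p = 0.00541). The mitochondrial list had adjusted p from 1.95e-28 to 0.982 without single libraries, turning downward without PBS replicate 1. At this depth and n, 60% of 1.2-fold changes were recovered in simulation, so smaller changes are often missed. The simulated changes were in well-counted genes only, so recovery for genes with few counts was not measured.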

Other observations

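Tests of the mitochondrial share, of the splits of the libraries, of genes of like abundance or length, of the length trend with principal transcripts, and of length and GC trends on the oxidative phosphorylation list were chosen only after the results were seen. Several matrix genes moved apart: TNC (log2 0.37), NID2 (0.34) and FBN1 (0.28) were the 3 higher and COL13A1 (log2 -0.24) was 1 of 2 lower genes of 33 in the matrix list (adjusted p = 0.266, 0.0352 upward without PBS replicate 2, and adjusted p = 0.722 with an estimated correlation). FBN1 did not pass with the length trend removed (log2 0.18, adjusted p = 0.162), nor did KRT8 (log2 -0.084, adjusted p = 0.115), which passed with the union of exons as length (0.0104). The intermediate filament genes KRT18 and KRT8 fell by 0.16 and 0.11 on the log2 scale, the only 2 of 18 genes of the epithelial junction list to pass. That list had an adjusted p of 0.695, with a median of 0.018 although the test pointed down. Exons of KRT18 and KRT8 overlap each other on opposite strands, and the strand setting of the counting is not given, so the 2 may not be independent. KRT18 had a log2 fold change of -0.10 with length and GC trends removed. MT2A fell from 255 ± 6.93 to 208 ± 5.01 CPM (log2 -0.29), and of 11 metallothionein and metal transport genes MT1X and the zinc exporter SLC30A1 (log2 -0.25) were also lower while the zinc importer SLC39A10 was higher (log2 0.22; 0.16 and adjusted p = 0.0641 with length and GC trends removed). That list had an adjusted p of 0.58, with a median of 0.035 although the test pointed down, and reads of metallothionein copies can be shared.

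In the immediate early list SPRY4 (log2 0.28) and SPRED1 (0.25) rose and DUSP1 and MYC (-0.15) fell, among 2 higher and 4 lower genes of 35 (adjusted p = 0.944). SPRED1 (log2 0.19, adjusted p = 0.0772) and MYC (log2 -0.10, adjusted p = 0.226) did not pass with the length trend removed, and SPRED1 did with the union of exons (0.0226). MYC had a log2 fold change of -0.098 without PBS replicate 2 (adjusted p = 0.485). MKI67 (log2 0.25), CENPF (0.19) and ASPM (0.19) rose and UBE2C (-0.12) fell in the G2/M list (3 higher and 2 lower of 55, adjusted p = 0.266). That list shifted upward with the length trend removed by the union of exons (adjusted p = 0.0118), and had adjusted p = 0.722 with an estimated correlation. With the length trend of principal transcripts removed MKI67 had a log2 fold change of 0.14 (adjusted p = 0.0441) and the other 3 did not pass, although CENPF did with the union of exons (log2 0.14, adjusted p = 0.0197). MKI67 had an adjusted p of 0.0682 without nanoparticle replicate 2, and the rising genes have transcripts of 12678, 10307 and 10887 bases against 850 for UBE2C. SYNE2 (log2 0.52) rose and TRPV2 (-0.15) fell among 19 mechanosensitive genes (adjusted p = 0.472), and TRPV2 had a log2 fold change of -0.14 after length removal (adjusted p = 0.0671). Among 25 heat shock genes 2 rose, DNAJB4 and HSPA1A, and 2 fell, HSPB1 and DNAJB6 (adjusted p = 0.973). The 2 that fell did not pass with the length trend removed (log2 -0.066 and -0.081, adjusted p = 0.289 and 0.207). DNAJB4 did not with length and GC trends removed (log2 0.26, adjusted p = 0.0926). Among 44 uptake and membrane repair genes CLTC rose, and CLTA and ANXA5 fell (adjusted p = 0.18), but with the length trend removed none of these 3 passed (log2 0.046, -0.068 and -0.083; adjusted p = 0.417, 0.298 and 0.239). With the union of exons as length that list shifted downward (adjusted p = 0.0219), and it had adjusted p = 0.722 with an estimated correlation. CTH (log2 0.48) and SLC7A11 were the 2 of 42 amino acid response genes to pass (adjusted p = 0.646), and GLA and GABARAPL1 the 2 of 45 lysosome genes (adjusted p = 0.397). No gene passed in the lists of glycolysis (adjusted p = 0.279, but 0.0292 downward without nanoparticle replicate 1, and adjusted p = 0.722 with an estimated correlation), fatty acid synthesis (0.563), interferon response (0.649), aryl hydrocarbon receptor targets (0.354), histones (0.311) or fibroblast markers (0.695). Markers of leukocytes, endothelium, airway epithelium and melanocytes had 3 or 4 tested genes each, none past the threshold. Endothelial markers summed to 64.7 and 63.6 CPM in PBS and 59.7 and 58.3 with nanoparticles, leukocyte markers to 15.4 and 14.96 against 14.1 and 16.3, and melanocyte markers to 3.86 and 4.01 against 4.12 and 4.83. Fibroblast markers summed to 92.5 and 93.8 CPM in PBS and 92.5 and 91.0 with nanoparticles, and alveolar and airway markers to 91.6 and 95.2 against 92.0 and 92.9.

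The lower ribosomal protein and oxidative phosphorylation mRNAs were weighed against depth, GC content and length. Depth would act alike on genes of the same abundance, but 340 other genes in the range of the ribosomal protein genes had a median log2 fold change of -0.018 and 2869 in that of the oxidative phosphorylation genes one of 0.0040, which argues against it; thinning (ribosomal protein median -0.076) keeps fold changes by construction and decides nothing. Removing the GC trend moved other genes (interquartile range of the move from -0.024 to 0.014) and left the medians at -0.074 (interquartile range -0.094 to -0.057) and -0.069 (-0.11 to -0.039), which argues against GC content alone (list adjusted p = 1.67e-18 and 7.8e-13, and adjusted p = 0.493 for each with an estimated correlation). Before any removal 704 other genes of like lengths had a median of -0.045 (interquartile range -0.084 to 0.0036), against -0.077 for the ribosomal protein list. Removing the length trend by the union of exons left the ribosomal protein median at -0.047 (interquartile range -0.074 to -0.020), where these 704 genes had -0.012. The list still passed (camera adjusted p = 2.23e-10 at the preset correlation). Both parts of the rule set beforehand as evidence against length were thus met, a median beyond -0.04 and a list past the threshold. With that measure the fold changes of 10935 other genes still went with principal transcript length (Spearman's rank correlation 0.13). Principal transcripts, taken up afterwards, left the median at -0.017 (-0.058 to 0.0052), where the same 704 genes had 0.0040 and the oxidative phosphorylation median was -0.033. Each list still passed at the preset correlation (adjusted p = 0.598 and 0.403 with an estimated correlation). The 2 measures do not settle the question of length. Length and treatment cannot be told apart here, because each library's length slope followed its group (-0.0239 and -0.0190 in PBS, 0.0140 and 0.0289 with nanoparticles), as did its GC slope (0.0111 and 0.0259 against -0.00468 and -0.0324), so RNA or library preparation that differed between groups and a treatment effect both stay open.

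For the NRF2 targets that rose, removing length and GC trends left the median log2 fold change of the 6 members past the threshold at 0.45, from 0.47, and all 6 still passed. In the same range of abundance 9247 other genes had a median of 0.0047. The 6 were picked by their rise in these data, so this comparison decides nothing about depth. Thinning left the 6 at 0.47 by construction. All 32 tested members had a median log2 fold change of 0.057 (interquartile range -0.014 to 0.16), and of 0.080 with length and GC trends removed. Of the 6 members 5 passed without nanoparticle replicate 1 as well as without nanoparticle replicate 2. Without either PBS library none of the 6 passed, although the log2 fold change of HMOX1 stayed between 0.91 and 1.37 over 17 settings. A hypothesis is that the antioxidant response may belong to the treatment, while a difference in culture between the groups was not tested.

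The higher mitochondrial mRNAs may reflect variation between libraries: the group means of the mitochondrial share differed by 0.0642 percentage points, 0.509 times the larger difference between replicates (0.126 points, nanoparticle; 0.109 points, PBS). Within each replicate number the share was higher with nanoparticles (0.328% against 0.272%, and 0.454% against 0.381%), which a comparison of group means leaves out. Whether the numbers mark pairs is not known. The biological alternative, a treatment effect, stays untested. Of the 3 splits of the 4 libraries into 2 and 2, 1 gave as many genes past the threshold as the real one, which was the real split with 407; the highest of the others gave 2. With 3 splits the share cannot fall below 0.05.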
